A study of Homo sapiens with 9 samples.

How the data were processed

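RNA of cells labelled as HaCaT was sequenced in pairs of 150 bases, per the labels' protocols, and 9 samples in 3 groups are described. The submitters' processing notes name FastQC, HISAT2, StringTie and the build GRCh38, without versions or roles. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so overlapping genes, antisense genes and close copies may have exchanged reads. Values were used from 2 deposited tables. The count table holds whole-number counts per gene and library as deposited by the authors, with no normalization. The other holds FPKM made by the authors. On the values used, each FPKM equalled the count divided by the annotated gene length and by a constant of the library, to within a relative difference of 4.69e-14. That constant was 1.05, 0.949 and 1.00 times the total of Nc1, Nc2 and Nc3, so the deposited FPKM carry a scaling between libraries whose method is not stated. FPKM of different genes are compared within a library and still carry the effects of GC content and of the annotated length.

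The tables name 9 columns of libraries. The stem Nc of 3 of them was read as an abbreviation for control, the group whose name it can shorten. The labels spell out no such abbreviation, so this is a reading. The other 6 columns of each table, 12 in both, were not used, because their names match no sample in the labels. Which treated group each stands for would have had to be taken from column order or from the values. For this reason none of the 3 planned comparisons between groups or their gene list tests was run. The planned overlap of the times would not change if the treated groups were swapped. It was not run either, since the columns were left unused. The planned comparisons were to use edgeR's quasi-likelihood test, and the 81 other settings listed for them were not run. Summaries of all columns, the unused ones included, were seen once when the tables were opened. The descriptions of the control libraries were chosen after that.

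The 26 gene lists with 342 different members and the 4 sets of markers of other cell types were fixed before the data were examined. The rule for named genes took the leading genes of each comparison, called members of the lists, all heme biosynthesis enzymes and the measured members of any list shown in a figure. With no comparison run, the last parts of the rule apply, and they admit each member of the 26 lists. Some list members are not reported here, in the text or the figures, while the counts of detected members cover whole lists except for heme biosynthesis. Which members are named as examples was decided after their values were seen. Genes were matched by symbol, and 4 symbols were matched by identifier. Of 58336 identifiers, 58216 were found in GENCODE release 29, and 98.7% of these had the same start and end there. Coordinates are those of the deposited table.

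A gene was called detected with at least 10 counts in each of the 3 libraries. CPM are counts scaled by the library's total. Scaling factors came from edgeR 4.0.16 (TMM) and, as an alternative, from DESeq2 1.42.0 (median of ratios), run in R 4.3.3. No edgeR or DESeq2 test was run. Variation beyond counting noise was tested per gene with a chi-square test of 1 rate in all libraries, given TMM sizes, with Benjamini-Hochberg adjustment at 0.05. The same test on each pair of libraries found between 2431 and 7033 genes, so no pair was treated as 1 library deposited again. For GC content and length, the longest transcript in GENCODE release 29 was used, over genes with at least 100 counts in each library. Of these, 9374 had a sequence and 2 did not. The ribosomal protein genes were compared with the median of the 50 genes nearest in GC content, length and level, with 95% intervals from 2000 bootstrap draws over genes. Pseudocounts of 0.01 FPKM or 1 count were used in plots alone. Other steps ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

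The chi-square test was tested on simulated Poisson counts of 13290 genes. On the first pass both simulations were run after the data, and they were then put ahead of it and everything was run again. With no gene changed it called 0. With 200 genes changed by 1.5 times in 1 library it recovered 147 and called 10 others, and with a change of 2 times it recovered 178 and called 15 others. The matched difference was tested on 100 simulated sets of 9374 genes with a trend on GC content, length and level. For a true shift of -0.3 it gave a mean of -0.31, and its intervals held the shift in 91 of the 100 sets, fewer than the nominal 95%. A form with a linear fit over the 50 nearest genes gave -0.29 and held it in 94. The simulated noise was independent between genes. These rates therefore do not cover genes that vary together, or transcript lengths that differ from those expressed. An earlier run of this test used a single simulated set and returned too small a shift, which led to the repeated sets and to the linear form, after the first result on the data had been seen. The set of ribosomal protein genes was also narrowed then, to leave out copies of these genes that carry names of their own.

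Alternatives were other minimums for detection, library totals or DESeq2 factors in place of TMM, a minimum mean of 100 counts and leaving out each library in turn. The list of 14 blood transcripts used in the closing section was written before their values were looked at. It holds HBM, which is also 1 of the 10 globin genes, so the list was summed without it as well. Intervals on counts are exact binomial intervals and cover counting error alone, since reads without molecular identifiers are not independent molecules.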

Results

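The study measured messenger RNA in cells labelled as HaCaT, an immortalised line of human skin keratinocytes, by RNA sequencing. Its labels describe 9 samples in 3 groups of 3. One group was the control, for which the labels give no 5-aminolevulinic acid or light setting. The other 2 groups received low-dose photodynamic therapy, in which cells are given 5-aminolevulinic acid, the precursor of the photosensitiser protoporphyrin IX, at 0.5 mmol per litre and are then exposed to red light of 635 ± 5 nm at 3 J per square centimetre. RNA of the treated groups was taken after 12 h or 48 h. The design asks how the transcriptome of treated cells differs from that of control cells at each time. The values of the treated samples were not used here, because the names of their columns match neither time in the labels, and no treated sample was compared with a control. What follows is the transcriptome of the 3 control libraries, named Nc1, Nc2 and Nc3, a stem that was read as an abbreviation for control. Errors are SD over these 3 libraries, with n = 3 throughout. Nothing in the labels says whether they came from separate cultures, so the spread between them may be technical.

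The libraries held 16989712, 16354678 and 16702425 counts. Of 58336 genes listed, 12717 had at least 10 counts in each library. Protein-coding genes took 97.3 ± 0.0821% of the counts and genes of the mitochondrial genome 8.23 ± 0.378%. The gene with the most counts was MT-CO1, a subunit of cytochrome c oxidase, at 21418 ± 1310.0 CPM. The translation elongation factor EEF1A1 stood at 10462 ± 1737 CPM, MT-CO3 at 10212 ± 390.3 CPM and the glycolytic enzyme GAPDH at 9749 ± 1262 CPM, in an order that differed between the libraries. These genes are named by their mean level, after their values were seen. A count of 0 allows up to 3 counts, which is 0.177, 0.183 and 0.18 CPM in Nc1, Nc2 and Nc3, with counting error alone considered.

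The 7 enzymes reported here of heme biosynthesis, the pathway that turns 5-aminolevulinic acid into protoporphyrin IX and then heme, were all detected. ALAS1, the housekeeping synthase that makes 5-aminolevulinic acid (ENSG00000023330, chromosome 3, 52198086 to 52214327, GRCh38), stood at 17.3 ± 0.465 FPKM. ALAD, which joins 5-aminolevulinic acid into porphobilinogen, stood at 6.33 ± 0.286 FPKM, and UROS at 8.95 ± 1.13 FPKM. UROD, the uroporphyrinogen decarboxylase (ENSG00000126088, chromosome 1, 45012147 to 45015575), had the highest level of the 7, at 61.6 ± 15.2 FPKM. CPOX stood at 15.4 ± 1.96 FPKM and PPOX, which forms protoporphyrin IX, had the lowest level, at 2.75 ± 0.288 FPKM. FECH, the ferrochelatase that inserts iron into protoporphyrin IX (ENSG00000066926, chromosome 18, 57548283 to 57586772), stood at 5.89 ± 0.757 FPKM. The ratio of UROD to FECH was 10.7 ± 3.16 and lay between 7.02 and 12.6 in the 3 libraries. That of FECH to PPOX was 2.17 ± 0.444. The counts of 4 of the 7 enzymes varied between libraries by more than counting noise, as did those of 56.8% of the 13290 genes tested.

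Of 12 genes of heme and iron handling, 10 were detected. The ferritin chains FTL and FTH1, which store iron, stood at 1179.7 ± 291 FPKM and 632 ± 51.2 FPKM, and the transferrin receptor TFRC at 87.7 ± 17.1 FPKM. The heme oxygenase HMOX1 stood at 2.5 ± 0.22 FPKM. ABCG2, an exporter that carries porphyrins, stood at 4.37 ± 0.505 FPKM. The 2 genes below the minimum were the iron exporter SLC40A1, with 7, 3 and 1 counts in Nc1, Nc2 and Nc3, and the porphyrin transporter ABCB6, with 13, 9 and 9.

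Of 17 targets of NRF2, the transcription factor of the antioxidant response, 16 were detected. Thioredoxin TXN, at 1222 ± 160.1 FPKM, and the peroxiredoxin PRDX1, at 1016 ± 151 FPKM, led the list. The quinone reductase NQO1 stood at 159 ± 28.9 FPKM, the cystine transporter SLC7A11 at 2.79 ± 0.631 FPKM and the sulfiredoxin SRXN1 at 1.71 ± 0.151 FPKM. TXN exceeded HMOX1 by 493 ± 86.8 times. Among 6 targets of the aryl hydrocarbon receptor, all detected, CYP1B1 stood at 17.6 ± 2.96 FPKM and CYP1A1 at 2.81 ± 0.138 FPKM. Of 6 metallothioneins, which bind zinc and copper, 4 were detected, with MT2A at 1115 ± 285 FPKM and MT1E at 748 ± 206 FPKM. MT1M had no count. Metallothionein genes are close copies of each other, so the split of counts among them is uncertain.

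Of 13 heat shock chaperones, 12 were detected. HSPB1 stood at 421 ± 68.1 FPKM, HSPA8 at 389 ± 72.8 FPKM and HSP90AA1 at 311 ± 45.2 FPKM. The stress-inducible HSPA1A stood at 77.8 ± 4.24 FPKM and its near-identical copy HSPA1B at 55.1 ± 2.1 FPKM, and the division of counts between this pair is uncertain. CRYAB had 3, 3 and 1 counts. All 13 genes of the ATF4 stress response were detected, from ASNS at 0.206 ± 0.0194 FPKM to the amino acid transporter subunit SLC7A5 at 801 ± 39.5 FPKM. ATF4 stood at 147 ± 18.8 FPKM, DDIT3 at 8.56 ± 0.807 FPKM and ATF3 at 2.25 ± 0.175 FPKM. All 13 chaperones and factors of the endoplasmic reticulum were detected, led by CALR at 329 ± 16.7 FPKM and HSPA5 at 124 ± 17.6 FPKM.

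**Figure D1:**
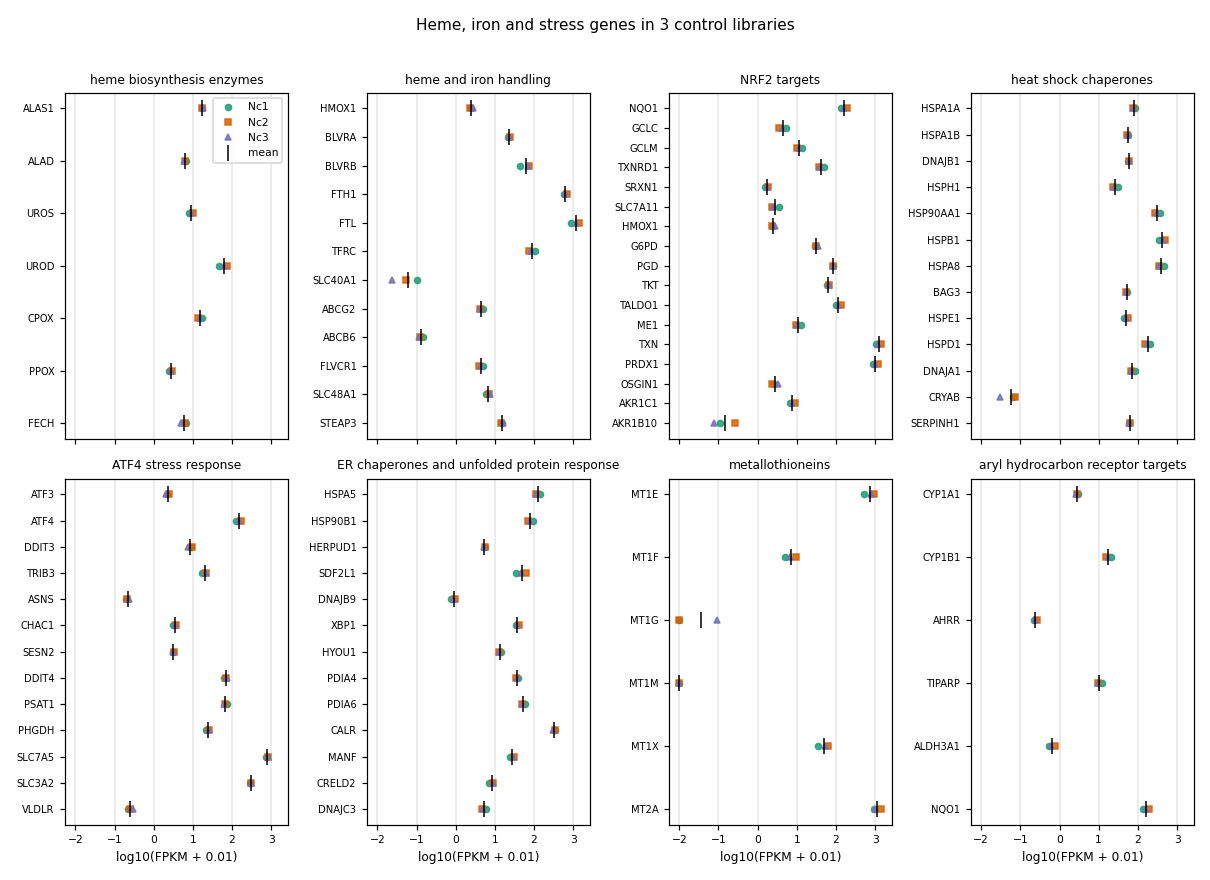
FPKM of the reported members of 8 gene lists in the control libraries Nc1, Nc2 and Nc3, on the scale log10(FPKM + 0.01), with each library as a point and the mean as a vertical bar. UROD is the highest of the 7 heme enzymes and PPOX the lowest, and TXN, FTL, MT2A and PRDX1 have means above 1000 FPKM.

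Of 13 genes of basal keratinocytes, 12 were detected. The hemidesmosome collagen COL17A1 stood at 114 ± 10.8 FPKM, the integrin ITGB4 at 57.7 ± 2.48 FPKM and the keratinocyte regulator TP63 at 22.4 ± 3.51 FPKM. KRT5, the type II keratin of basal cells, stood at 94.7 ± 5.99 FPKM. KRT14, which pairs with KRT5 in basal epidermis, had 9, 8 and 15 counts in Nc1, Nc2 and Nc3, or 0.28 ± 0.0971 FPKM. Over the whole keratin family, the 5 genes KRT7, KRT8, KRT13, KRT18 and KRT19 took 92.2 ± 0.731% of the counts. KRT7, a keratin of simple epithelia, stood at 1024 ± 132 FPKM. These 5 genes were chosen after their values were seen.

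Of 19 genes of keratinocyte differentiation, 7 were detected and 8 had no count in any library, among them KRT1, LORICRIN and DSG1. KRT10 stood at 15.2 ± 1.19 FPKM and involucrin, IVL, at 4.29 ± 0.559 FPKM. Filaggrin, FLG, had 19, 15 and 25 counts. Of 13 genes of activated keratinocytes, 9 were detected. The lipocalin LCN2 stood at 589 ± 107 FPKM, S100A9 at 56.4 ± 14.6 FPKM and KRT6A at 48.8 ± 2.3 FPKM. KRT16 stood at 0.354 ± 0.189 FPKM and KRT17 at 0.747 ± 0.216 FPKM. The 3 KRT6 genes are close copies, and their division is uncertain.

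Of 18 inflammatory cytokine genes, 14 were detected. The chemokines CXCL1 and CCL2 stood at 86.3 ± 5.65 FPKM and 84.5 ± 15.7 FPKM, and the interleukin IL1B at 64.8 ± 6.24 FPKM. IL6 stood at 0.441 ± 0.0601 FPKM, and TNF had 9, 8 and 1 counts. Of 16 interferon-stimulated genes, 15 were detected, with ISG15 at 96 ± 24.2 FPKM and MX1 at 0.638 ± 0.111 FPKM. CXCL10 had 12, 11 and 4 counts. Of 15 secreted growth factors, 14 were detected. IGFBP3, which binds insulin-like growth factors, stood at 288 ± 7.44 FPKM, the epidermal growth factor receptor ligand AREG at 20.6 ± 1.89 FPKM and VEGFA at 4.22 ± 0.0995 FPKM.

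**Figure D2:**
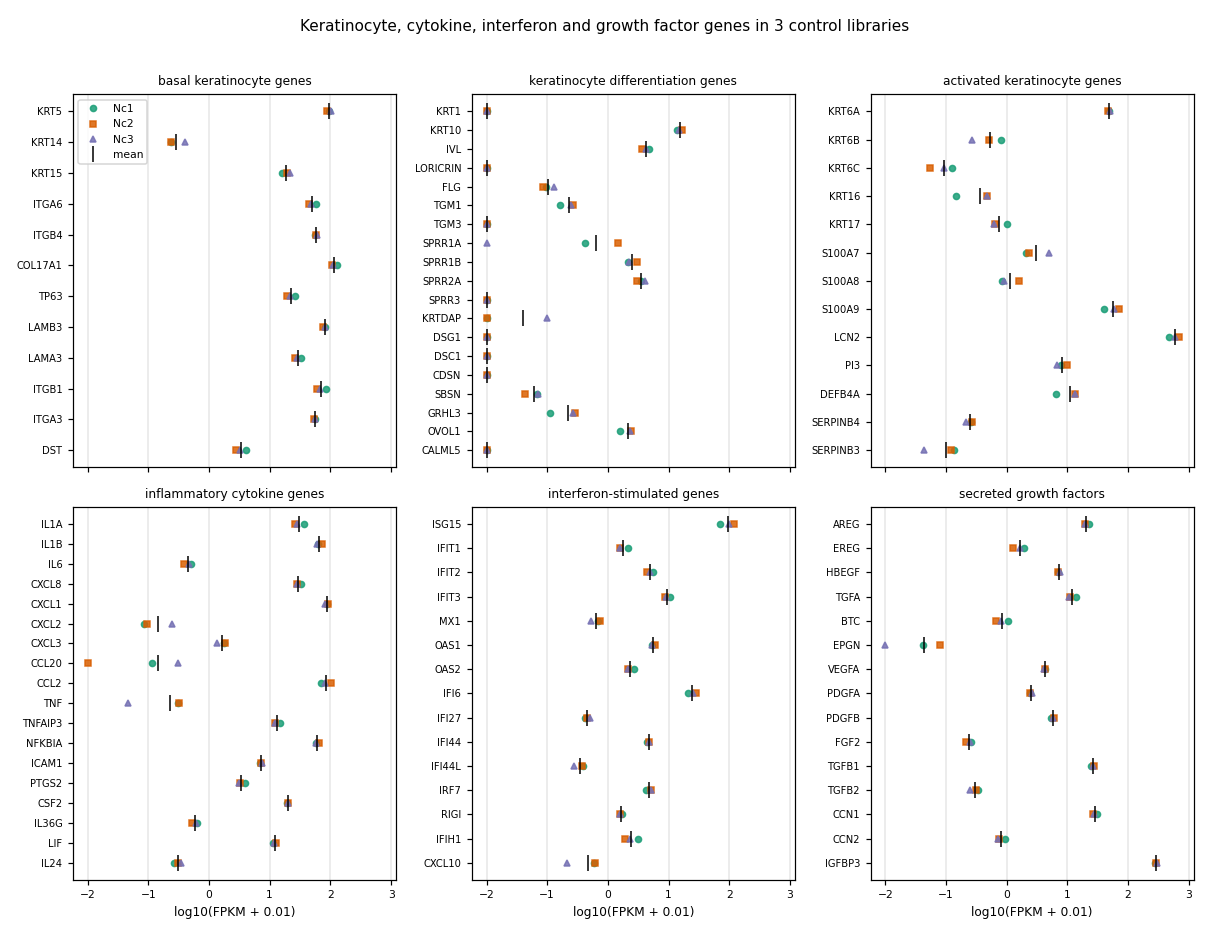
FPKM of the reported members of 6 gene lists in the control libraries Nc1, Nc2 and Nc3, on the scale log10(FPKM + 0.01), with each library as a point and the mean as a vertical bar. KRT14 lies far below KRT5, and 8 of the 19 differentiation genes lie at 0 in each library.

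All 15 mitosis genes and all 16 DNA replication genes were detected. The ubiquitin-conjugating enzyme UBE2C stood at 153 ± 25.3 FPKM, CDC20 at 151 ± 8.03 FPKM and MKI67 at 23.5 ± 3.31 FPKM. The replicative helicase subunit MCM7 stood at 369 ± 9.82 FPKM and the sliding clamp PCNA at 239.6 ± 14.3 FPKM. Of 15 targets of p53, 14 were detected, with PHLDA3 at 44.1 ± 9.01 FPKM, the cell cycle inhibitor CDKN1A at 34.7 ± 5.59 FPKM and MDM2 at 1.01 ± 0.2 FPKM. Of 14 immediate early genes, 13 were detected. IER3 stood at 105 ± 13.2 FPKM, JUNB at 87.9 ± 11.8 FPKM and FOSL1 at 72.2 ± 1.82 FPKM, while FOS stood at 1.49 ± 0.148 FPKM and FOSB at 0.561 ± 0.0116 FPKM.

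All 13 messenger RNAs of the mitochondrial genome were detected, from MT-ND6 at 2301 ± 324 FPKM to MT-CO1 at 13917 ± 1273 FPKM. All 12 nuclear genes of the respiratory chain were detected, from NDUFA9 at 2.42 ± 0.212 FPKM to ATP5F1B at 653 ± 32.9 FPKM. Of 15 hypoxia and glycolysis genes, 14 were detected. LDHA stood at 380.1 ± 49.6 FPKM, PGK1 at 159 ± 11.2 FPKM and NDRG1 at 56 ± 2.48 FPKM, whereas the hypoxia marker CA9 had 4, 1 and 6 counts. All 15 genes of cholesterol synthesis were detected, with FDFT1 at 82.1 ± 5.71 FPKM and DHCR7 at 35.8 ± 2.3 FPKM. All 13 autophagy genes were detected, with the cargo receptor SQSTM1 at 91.7 ± 8.67 FPKM.

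**Figure D3:**
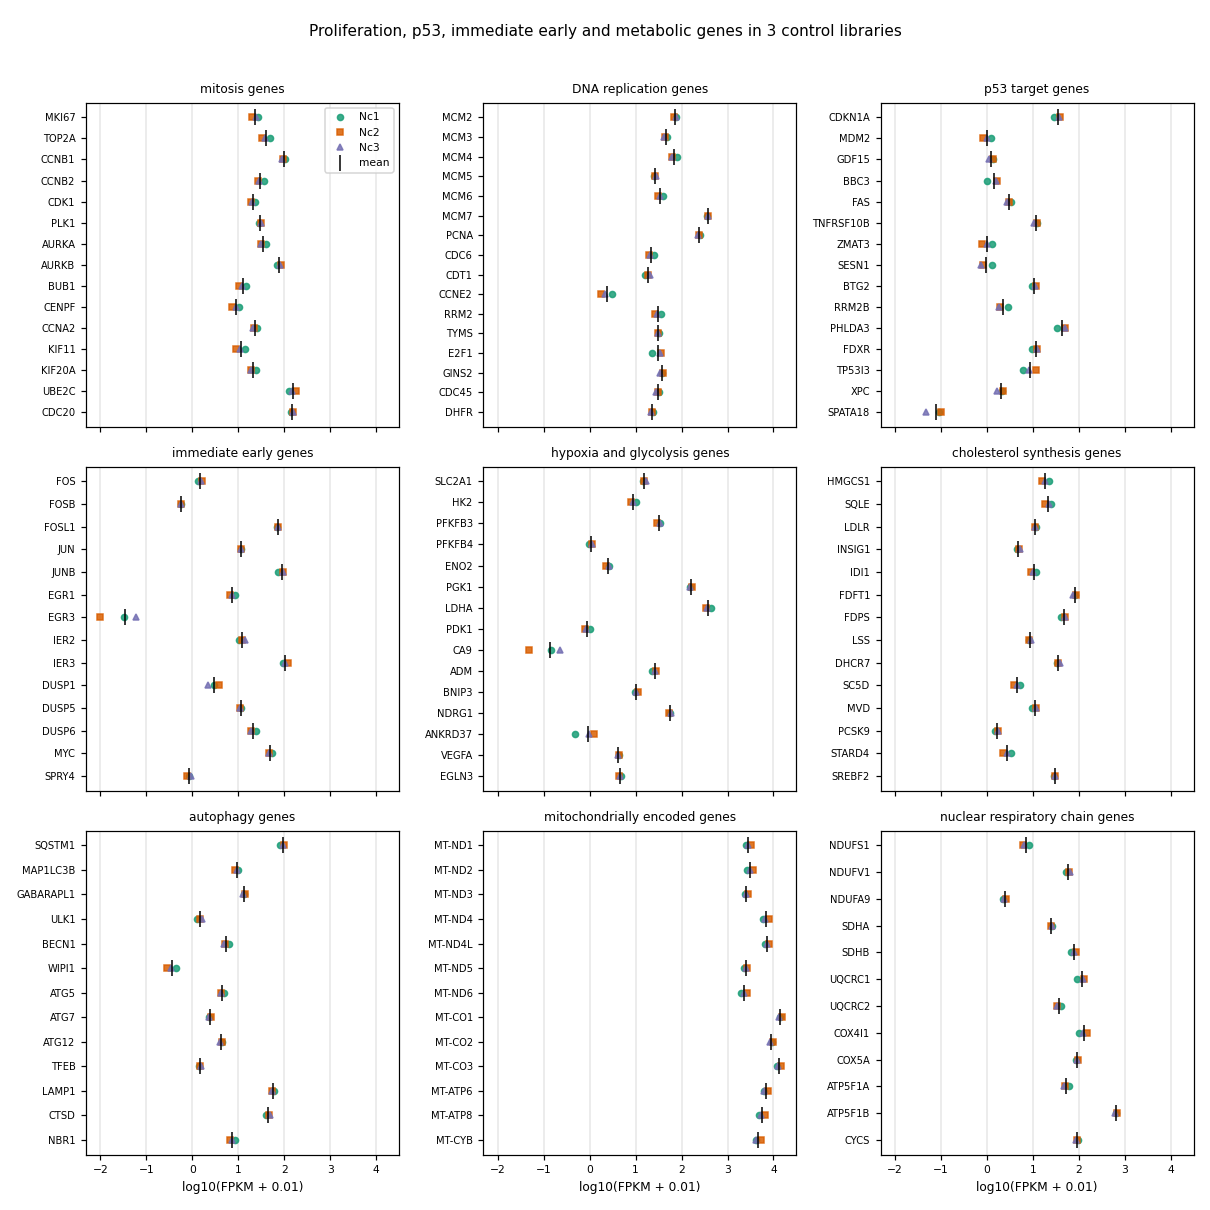
FPKM of the reported members of 9 gene lists in the control libraries Nc1, Nc2 and Nc3, on the scale log10(FPKM + 0.01), with each library as a point and the mean as a vertical bar. Each mitosis and DNA replication gene was detected, with UBE2C and MCM7 the highest of their lists.

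Of 14 matrix proteases and inhibitors, 10 were detected. TIMP1, an inhibitor of matrix metalloproteinases, stood at 90.3 ± 9.52 FPKM, MMP14 at 48 ± 1.34 FPKM and PLAU at 46 ± 2.53 FPKM. MMP9 stood at 0.513 ± 0.0426 FPKM, and MMP3 had no count. Of 12 structural matrix genes, 10 were detected, with fibronectin FN1 at 64.1 ± 5.02 FPKM and THBS1 at 46.5 ± 4.09 FPKM. Of 11 genes of the mesenchymal transition, 7 were detected. TGFBI stood at 134 ± 8.88 FPKM and SNAI2 at 30.3 ± 4.28 FPKM. Vimentin, VIM, stood at 0.836 ± 0.187 FPKM, and TWIST1 had 1, 1 and 0 counts.

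**Figure D4:**
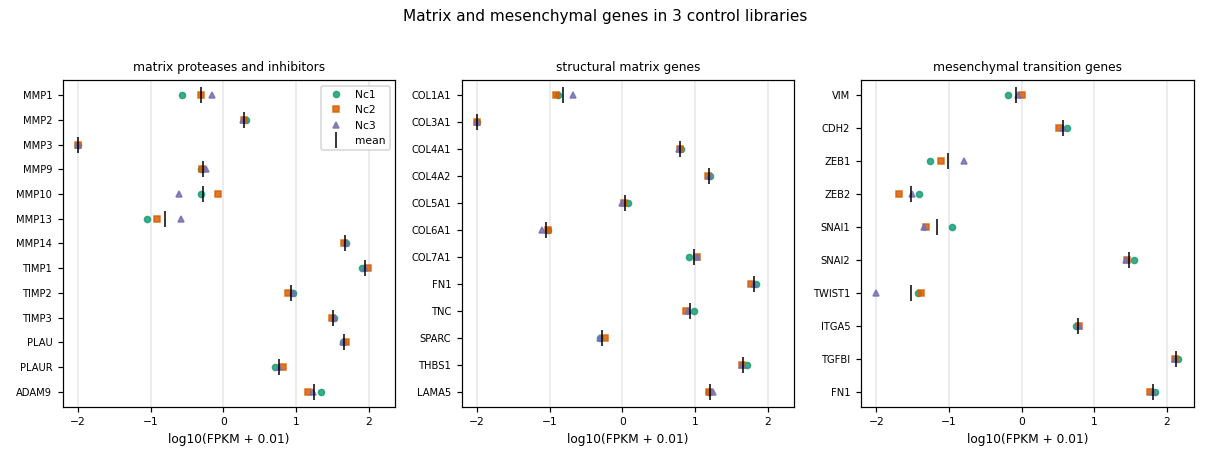
FPKM of the reported members of 3 gene lists in the control libraries Nc1, Nc2 and Nc3, on the scale log10(FPKM + 0.01), with each library as a point and the mean as a vertical bar. TGFBI lies above 100 FPKM, and MMP3 and COL3A1 lie at 0 in each library.

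Markers of other cell types were low. The 8 fibroblast markers summed to 52, 63 and 62 counts in Nc1, Nc2 and Nc3, the 6 endothelial markers to 100, 108 and 88, and the 6 melanocyte markers to 14, 22 and 23. The 6 immune markers summed to 187, 132 and 27 counts. PTPRC, the leukocyte common antigen, had 103, 78 and 12 counts and lysozyme, LYZ, had 47, 22 and 0. The beta globin gene HBB had 6700, 6665 and 2 counts, HBA2 had 551, 637 and 1 and HBA1 had 85, 155 and 0. The globin genes were chosen after their values were seen, and HBA1 and HBA2 are near-identical copies. Nc1 and Nc2 thus carried globin counts that Nc3 did not, and the counts of PTPRC and LYZ lay mostly in the same libraries.

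**Figure D5:**
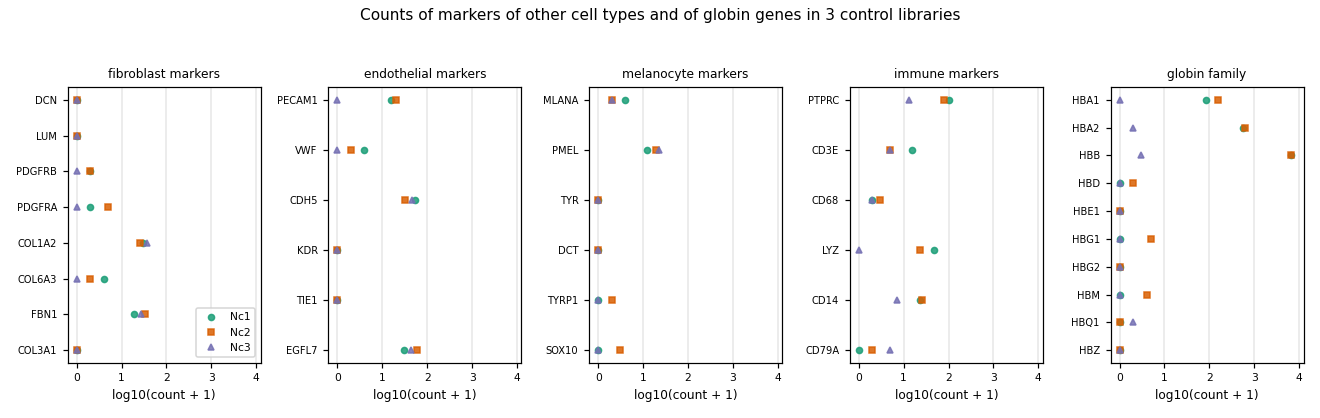
Counts of markers of 4 other cell types and of 10 globin genes in the control libraries Nc1, Nc2 and Nc3, on the scale log10(count + 1), with each library as a point. HBB, HBA2 and HBA1 are high in Nc1 and Nc2 and at most 2 counts in Nc3.

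The 3 libraries were not copies of each other. Of 13290 genes with a mean of at least 10 counts, 7543 varied by more than counting noise, by a chi-square test on the counts with a Benjamini-Hochberg false discovery rate of 5%. Without Nc1 the count was 2431 genes, without Nc2 it was 6005 and without Nc3 it was 7033. Over 9706 genes with a mean of at least 100 counts, the median coefficient of variation was 11.8%, against 4.11% from counting alone. Nc1 stood farthest from the others. Relative to the mean of the other libraries, the fifth of genes with the lowest GC content had a median log2 difference of 0.28 in Nc1, and the fifth with the highest had -0.34. The same medians were -0.21 and 0.19 in Nc2 and -0.07 and 0.15 in Nc3. As each library is set against the others, the differences of the libraries depend on each other. For the fifth of genes with the shortest transcripts and the fifth with the longest, the medians were -0.34 and 0.21 in Nc1, 0.28 and -0.17 in Nc2 and 0.06 and -0.02 in Nc3. The 75 ribosomal protein genes had a median log2 difference of -0.59 in Nc1, 0.47 in Nc2 and 0.10 in Nc3, where the medians of all 9374 genes were 0.02, -0.01 and 0.00. UROD, FTL and MT2A are among the list members whose counts varied by more than counting noise.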

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

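All alternatives here were chosen after the data were seen, and the planned ones, which belong to the comparisons between groups, were not run. No paired analysis was possible because the columns used belong to 1 group. The count of 12717 detected genes stayed within 1.5 times under each other minimum, between 10081 with at least 1 FPKM and 16735 with at least 1 count in each library, and lay between 12870 and 12928 with 1 library left out. The 300 detected list members became 267 and 324 under these minimums, and 300 to 303 with 1 library left out. The 7543 genes varying beyond counting noise became 8217 with library totals, 7516 with DESeq2 factors and 6870 with a minimum mean of 100 counts. With 1 library left out they ranged from 2431 without Nc1 to 7033 without Nc3, so this count depends on Nc1. Fewer libraries also give the test less to detect, and how much of the drop that makes was not tested. The median log2 difference of the ribosomal protein genes in Nc1 was -0.59, and it was -0.43 with library totals, which move the median of all genes to 0.19, -0.35 against matched genes and -0.30 with the linear fit. Of the FPKM of 367 genes in the lists and marker sets, none moved by 1 SD with library totals in place of the authors' scaling. The authors' constants averaged 1.0003 times the totals. This change therefore nearly cancels in a mean over the libraries and shows little about stability. With 1 of 3 libraries left out, a mean cannot move by more than 0.577 SD, so that comparison shows nothing about stability. The largest such move of a detected gene was 1.41 times. Depth limits the lowest genes: one without a count in a library is bounded at 3 counts there.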

Other observations

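The tests of library depth, of globin copies and of GC content were chosen after the results they bear on were seen. The tests of the blood list and of keratin sequence were written after the patterns they bear on were seen, but before their own results. The blood prediction also names S100A8, whose counts had been seen. The design gives no groups among the control libraries, so no biological explanation was tested for any pattern below.

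Among S100 calcium-binding proteins, which the lists cover in part, 13 of 19 genes were detected. S100A2 stood at 2718 ± 781 FPKM, S100A6 at 1479 ± 369.7 FPKM and S100A11 at 1429 ± 205 FPKM, with S100A8 at 1.11 ± 0.427 FPKM. Of 55 keratin genes, 13 were detected and 29 had no count in any library. KRT19 stood at 633 ± 67.6 FPKM, KRT13 at 533 ± 78.7 FPKM, KRT18 at 343 ± 31.2 FPKM and KRT8 at 334 ± 27.8 FPKM, all above KRT5. The cell cycle inhibitor gene CDKN2A stood at 24.1 ± 6.6 FPKM. These genes were chosen after their values were seen.

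Globin genes summed to 7336 counts in Nc1, 7465 in Nc2 and 4 in Nc3. Depth was argued against, since the highest library total was 1.04 times the lowest, and so were reads moved between globin copies, since the sum over the 10 genes in Nc3 was 0.0545% of that in Nc1. A search over all genes, except those of the Y chromosome and XIST, for at least 20 counts in 2 libraries and at most 2 in the third found 7 genes low in Nc3, none low in Nc1 and none low in Nc2. They were HBB, HBA2, HBA1, FCGR3B, CSF3R, LYZ and CXCR2. RNA from blood cells is a candidate source that stays open. The 14 blood transcripts, 6 of red cells and 8 of leukocytes, summed to 180, 191 and 36 counts. Without the globin gene HBM they summed to 180, 188 and 36. Either sum was at least 4.92 times the rate of Nc3 in both other libraries. However, S100A8, abundant in granulocytes, had 15, 25 and 15 counts. Its rate ratio was 0.983 in Nc1 (95% interval 0.448 to 2.16) and 1.7 in Nc2 (0.863 to 3.47). Both intervals include 1, so a rise in S100A8 is not shown in either library. A rise of up to 2.16 times in Nc1 or 3.47 times in Nc2 is not excluded. A rise as large as that of the blood list lies outside both intervals. Nc3 holds S100A8 counts as well, so how far blood RNA would raise the ratio is not known. In Nc3, 1 of the 14 transcripts exceeded 3 counts, CCL5 with 32, which these cells may express themselves. CCL5 held most of the 36 counts of Nc3, so the ratio of 4.92 depends on this gene. It had 48, 57 and 32 counts, a smaller relative difference than that of the whole list. CCL5 thus pulls the ratio down. The 6 red cell transcripts alone summed to 25, 29 and 0 counts.

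Ribosomal protein genes were lower in Nc1, by the median given above, in 70 of 75 genes. In Nc2, 73 of the 75 genes were higher, and in Nc3 62 were. Each library is set against the mean of the others, so these differences depend on each other. Whether Nc1 is low or Nc2 is high was not tested. Across genes, which are not independent replicates, the log2 difference of Nc1 had a Spearman correlation of -0.69 with GC content and of 0.50 with transcript length. The difference from genes matched on GC content, length and level was still -0.35 (95% interval -0.43 to -0.26). Such intervals take the genes as independent and do not cover error between libraries. For the longest annotated transcript of each gene, the remaining difference argues against the trends as the whole cause. The trends may still account for part of the difference. The match would be off where a shorter transcript was expressed, and this was not tested. The difference from the median of all genes, -0.62 (95% interval -0.68 to -0.51), is by construction the same under TMM, library totals and DESeq2 factors. Against matched genes the same median was 0.25 in Nc2 and 0.08 in Nc3. A property that the match leaves out, such as differences in RNA handling, was not tested.

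KRT14, KRT16 and KRT17 had few counts beside KRT5, which exceeded KRT14 by 359 ± 89.1 times in FPKM. Exact sharing of 150-base reads with other keratins or with pseudogenes is argued against as the cause. At least 99.26% of the 150-base stretches of the longest transcript of each of the 3 genes occur in no other gene's transcripts. Stretches that differ by a mismatch were not counted as shared, so how reads were placed among near copies was not tested. The pseudogenes KRT16P2, KRT16P3 and KRT17P1 held at most 2 counts in a library. Basal keratinocytes are known to express KRT5 together with KRT14. VIM, at 0.836 ± 0.187 FPKM, was low as well, while KRT7, KRT13, KRT19 and CDKN2A had the levels given above. Whether this profile as a whole belongs to the line named in the labels, to its culture or to another line was not tested, since no reference profile was used here, and the values of the treated samples were not used here.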
